A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

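The measured material was 1 library of BY4741 cells, fixed with 2% formaldehyde for 10 min, digested with MspI for 2 h at 37 °C and ligated for 2 h at 16 °C, per the labels. The deposited files hold other data than counts or levels: unaligned reads in FASTA form, 1 record per read, with no quality values, positions or numeric values. Per the labels, the authors' software sorted the reads by the presence or absence of the MspI site. In the files, all 373386 reads of the group with the site held CCGG (1 site in 361220, 2 in 11585, 3 in 567 and 4 in 14), and 0 of the 10622337 reads without it did. All reads were 36 bases long. Uncalled bases occurred in 2.48% of the site reads and 3.95% of the others. Identical sequences made up 26.0% and 30.0% of reads. With 1 library there was no grouping to test, so the comparisons are between classes of ends and of sequence inside the library.

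No genome sequence was used here, since none was given with the data. Reads of both groups were assembled with programs written for this purpose in C++ (g++ 11.4.0) and Python 3. Read errors were corrected with k-mers of 17 bases seen in at least 4 reads, and corrected reads were assembled with k-mers of 21 bases seen at least 2 times. The paths were extended with read overlaps, merged where they overlapped, and polished by alignment with up to 3 mismatches. Site reads entered the assembly only where the site with 6 bases on each side was seen from at least 2 read starts, so that ligation junctions would not be built in. Several assembly settings were tried, and the one used was chosen on N50 and on how many more contigs were placed on the real gene table than on a decoy table, never on junctions. The assembly had 13386 contigs with 11807382 bases, an N50 of 1537 bases, a longest contig of 9586 bases and 13656 MspI sites. Reads without a site were aligned to it with bwa 0.7.19 (up to 2 mismatches, no gaps) and read with samtools 1.23.1. In all, 7823225 reads aligned, 5286152 of them without a mismatch (49.8% of the group).

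Depth was the number of reads aligned without a mismatch per start position. For located genes, start positions whose window holds CCGG were left out. For pieces, and so for the classes and the median, they were kept. No read without a site can match exactly there. Contigs were divided into 14602 pieces wherever depth changed by at least 2.5-fold, and copies are depth divided by the median of pieces with at least 1000 start positions. Pieces were classed by copies and GC content after the distribution of depth had been seen. The classes were rDNA from 100 copies, 2-micron plasmid from 50 to 100, high-copy repeats from 8 to 50, low-copy repeats from 1.6 to 8, and single-copy sequence from 0.4 to 1.6. A class below single-copy held the 322 pieces under 0.4 copies. It stood at 0.292 copies with 4.18 MspI sites per kb, counting only sites with at least 20 bases of contig on both sides. What these pieces are was not tested. Its ends entered the shuffles and the test of mitochondrial partners, but not the tests of class pairs. Mitochondrial pieces had less than 20% GC at any depth, or less than 32% GC at 2.5 to 20 copies. Short known sequences of ribosomal RNA fell in the rDNA class apart from some short pieces in the 2-micron and high-copy classes.

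A read with exactly 1 site was split there, and each part was matched without mismatch to the MspI ends of contigs with at least 20 bases on both sides of the site. Each part needed at least 12 bases beyond the site. A read counted as a junction only when each part differed by at least 3 bases from the sequence that continues the other part, which left out 12484 reads close to the intact site. Identical reads counted once. Junctions were compared with 100000 random pairings of the same ends (two-sided permutation test), with exact Poisson intervals on the ratio of found to expected. Shares have Wilson intervals, Fisher's exact test was used for the partners of mitochondrial ends, and p values within each family were adjusted after Benjamini and Hochberg. Tests of contig pairs were exact Poisson tests on the product of the end counts. The slope with distance used 9 bins from 1 kb to 1000 kb and 2000 bootstrap draws over junctions.

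Contigs of at least 500 bases were placed on chromosomes by the spacing of start and stop codons of their open reading frames, compared with gene lengths and gaps in the R64 gene table of strain S288C (6477 genes). Its coordinates were used for placement only. With at least 3 gene boundaries and a score margin of 5, 641 contigs (15.2% of bases) were placed, against 20 on the decoy table (3.12%). Genes were named from the 367 contigs with at least 4 boundaries, where the decoy table placed 1 (0.272%). Proteins written from general knowledge, checked against the lengths in the gene table, were searched in all frames of the reads as stretches of 9 residues. The MET17 probe was 1344 bases long with its stop codon against 1335 in the table. COX1 and COB are longer in the table, and FLP1 and TYA1 had no length there, so those 4 were not checked. Contigs were searched with tblastn of BLAST+ 2.17.0 at 90% identity or more.

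Genes to be named were set by a rule written before the data were examined. It names the 4 deleted markers, the up to 10 genes with the lowest and the highest depth among those with at least 200 start positions, genes at repeated junctions, up to 5 members of each gene list, the nuclear genes joined to the mitochondrion, and the mitochondrial genes. Genes joined to the mitochondrion were taken from whole contigs instead of single fragments. ASP3 as a family of 4 genes was looked up after its value was seen.

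The method was tested on simulated reads with 1% errors. Of 20000 simulated intact sites, 0 were called junctions, and of 3000 simulated junctions 1838 (61.3%) were recovered, with none called intact. These reads were made from the assembled ends that they were then matched to. Gaps and wrong joins in the assembly were not simulated, so the test does not cover false junctions from them. A planted excess of plasmid pairs was found at 88.1-fold, and 0 of 100 random pairings gave a p below 0.05. The random pairings tested only plasmid pairs among the simulated ends. Such pairs were rarer there than in shuffles of the data, so a p below 0.05 was unlikely in advance. The planted excess was also larger than the one found in the data. Neither number therefore gives the error rate or the power of the plasmid test on the data. Steps in depth were found in 200 of 200 contigs, and 0 of 200 flat contigs were divided.

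Left out for want of a genome sequence were junctions between centromeres and between chromosome ends, junctions within gene lists, depth near centromeres and chromosome ends, and bins along chromosomes, for which pairs of contigs took their place. No paired analysis was possible because there is 1 library. Alternatives were another number of bases beyond the site (10 or 14), every read counted, 1 mismatch per part, junctions within 1 kb left out, another background, another depth measure and, chosen after the data were seen, a placement margin of 8, a 28% GC limit for mitochondrial pieces, repeated end pairs left out and cut-end reads left out. Statistics used NumPy, SciPy and pandas, and figures used Matplotlib.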

Results

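The data were 36-base reads from 1 genome conformation capture library of exponentially growing Saccharomyces cerevisiae BY4741. In this assay, formaldehyde fixes DNA that lies close together in the nucleus, the enzyme MspI cuts it at CCGG, and ligase joins the free ends, so that a read across a rejoined CCGG can hold sequence from separate places. The cells were grown in medium with 2% glucose at 30 °C to an A600 of 0.6. The deposited reads were divided into those with an MspI site and those without one. The group with the site held 373386 reads, of which 276153 were distinct, and the group without it held 10622337 reads, of which 7431142 were distinct. These are parts of the same library, so n = 1 library, there were no replicates, and every interval below is a 95% interval that covers counting error only. The question of the series is which parts of the yeast genome lay near each other in the cell.

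The first comparison asked whether the enzyme's site was read as often as the assembled contigs offer it. Reads with a site made up 3.396% of all 10995723 reads (Wilson interval 3.39% to 3.41%). In contigs assembled from the same reads, 3.42% of windows of the read length held CCGG, so the ratio of found to expected was 0.993. Site reads entered the assembly only in part, so the contigs may hold fewer sites than the genome. The expected share may therefore be too low for the genome, by an amount that was not tested. When each sequence class was weighted by its depth, 3.71% were expected and the ratio was 0.915. With identical reads counted once, the share was 3.58% and the ratio to the unweighted expectation was 1.05. Against the weighted expectation that counting gave 0.965. The direction of the difference therefore depended on how reads were counted under the unweighted expectation, and both countings lay below 1 under the weighted one.

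The second comparison asked what lies on both sides of the site. Of the 276153 distinct site reads, 22656 had both parts matched to MspI ends of the assembly. In 19360 of these the parts were neighbours in the genome, so the site had been left intact or closed again. The other 3296 joined ends that are not neighbours and are called junctions here. They made up 14.5% of the reads with both parts matched (14.1% to 15.0%). The 12484 reads close to an intact site are left out of both numbers, and counting them as intact would lower the share. Most site reads gave no answer, because 193746 of them had fewer than 12 bases on 1 side of the site. Among the junctions, 3036 joined different contigs, 185 joined separate fragments of the same contig, 71 closed a fragment into a circle, and 4 joined copies of the same end. Parts written backwards matched an end in 0.0454% of cases, which is the rate of matching by chance.

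Circles depended on fragment length. The median fragment closed into a circle was 1089 bases long, against 298 bases for all 6150 fragments with both ends in the assembly. Fragments shorter than 250 bases gave 1.45 circles per 1000 fragments (0.394 to 3.70, exact Poisson), those of 500 to 1000 bases gave 15.9 (9.84 to 24.3), and those of 1000 to 2000 bases gave 64.8 (46.1 to 88.6). The 93 longer fragments gave 21.5 (2.60 to 77.7), from 2 circles.

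The third comparison asked whether ends that are close on a chromosome were joined more often than ends that are far apart. They were. Single-copy ends of the same contig formed 168 junctions, where 0.421 were expected when the partners of all 3221 junctions other than circles and same-end joins were shuffled, a 399-fold excess (341 to 464), or 196-fold with junctions within 1 kb left out. The two-sided permutation p was 2e-05, the smallest that 100000 shuffles can give. Rates are given here as junctions per 1000000 possible end pairs. Within a contig the rate was 3516 at distances below 0.5 kb, 4740 at 1 to 2 kb and 2033 at 4 to 10 kb. Ends of different single-copy contigs gave a rate of 8.62 (8.27 to 8.98).

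Part of the contigs could be assigned to a chromosome, which allowed longer distances to be tested. Both ends of 122 junctions lay on contigs placed on the R64 gene table of strain S288C, and 87 of these junctions (71.3%, 62.7% to 78.6%) fell within a single chromosome. Of the placed junctions from shuffled partners, 7.05% did. In counts, the 87 stood against 5.24 expected, 16.6-fold (13.3 to 20.5), with a permutation p of 2e-05, again the smallest possible. This ratio includes an excess of junctions with both ends placed (122 against 74.3), and much of it came from junctions inside a contig. Among the 60 placed junctions between different contigs, 25 (41.7%, 30.1% to 54.3%) stayed on the same chromosome, against 6.87% of shuffled ones. In counts, 25 stood against 5.09 expected, 4.91-fold (3.18 to 7.25), and that result had the same smallest permutation p.

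On placed contigs the rate fell with distance. It was 5325 at 1 to 2.15 kb, 1091 at 4.64 to 10 kb, 247 at 10 to 21.5 kb and 29.2 at 21.5 to 46.4 kb, the last of these from 1 junction. The slope of log rate on log distance was -1.63 (bootstrap interval -1.84 to -1.01, 65 junctions). It was fitted to the bins that held a junction, which leaves out the bins beyond 46.4 kb. Without the bin of 1 junction the slope was -1.28. No junction was found between placed ends of the same chromosome 50 kb or more apart, among 507176 end pairs, which allows a rate of up to 7.27. Placed ends of different chromosomes gave 35 junctions, a rate of 4.51 (3.14 to 6.28). Whether distant loci of a chromosome met more often than loci of different chromosomes was therefore not detectable at this depth.

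**Figure D1:**
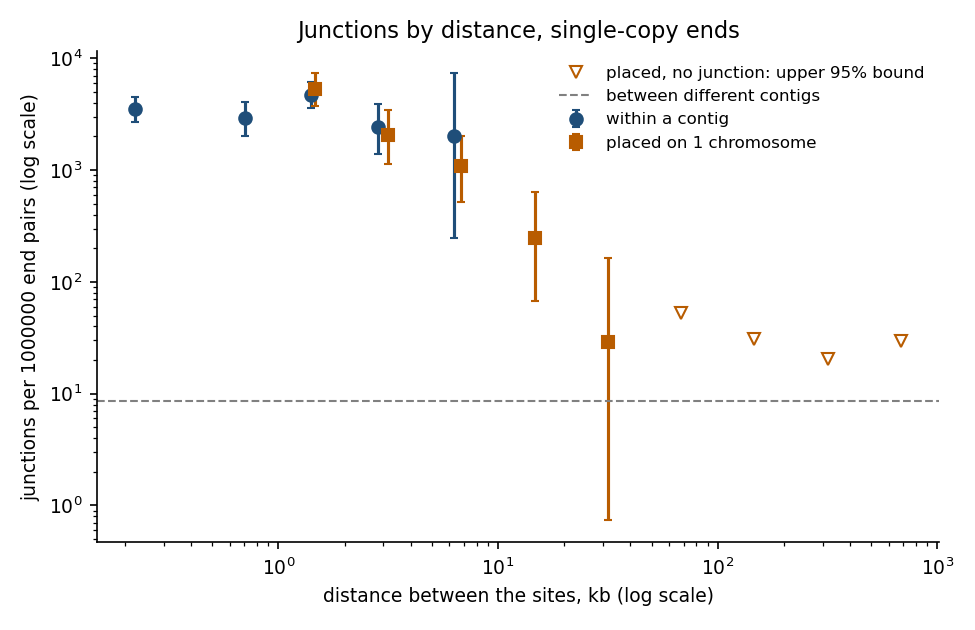
Junctions per 1000000 possible end pairs (vertical axis, log scale) against the distance between the sites in kb (horizontal axis, log scale), for single-copy ends in the same contig (circles) and on contigs placed on the same chromosome (squares), with 95% Poisson intervals; open triangles are upper bounds of bins without a junction and the dashed line is the rate between different contigs. On placed contigs the rate fell from 5325 at 1 to 2.15 kb to 29.2 at 21.5 to 46.4 kb, against 8.62 between different contigs.

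The fourth comparison asked whether the repeated parts of the genome kept to themselves. The ribosomal DNA (rDNA), an array of nearly identical units, joined itself more often than shuffled partners. It had an end in 287 of the 3221 junctions (8.91%, 7.97% to 9.94%). Its ends met each other in 47 junctions against 7.33 from shuffled partners, a 6.41-fold excess (4.71 to 8.52, adjusted p 6e-05). The excess was 5.82-fold with junctions within 1 kb on a contig left out. Shuffled partners take no account of distance along the DNA, so joins between neighbouring fragments of a unit count in this excess. Ends of rDNA met single-copy ends in 191 junctions, where 283 were expected, a ratio of 0.674 (0.582 to 0.777, adjusted p 6e-05). The 2-micron plasmid, a circular DNA of yeast nuclei, showed the same pattern. Its ends joined each other 48 times against 3.08 expected, 15.6-fold (11.5 to 20.7), and joined single-copy ends 104 times against 193 expected, a ratio of 0.540 (0.441 to 0.655), both with an adjusted p of 6e-05. In the shuffles every end keeps its number of junctions, so joins within a class leave fewer of its ends for other classes. The shortfalls of rDNA and plasmid with single-copy ends are therefore not separate evidence. The plasmid gene FLP1 lay on pieces with 3 MspI sites that held 99 junction ends. Permutation tests covered all 21 pairs of classes other than the one below single-copy. Of their Benjamini-Hochberg adjusted p values, 6e-05 is the smallest.

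Between the rDNA and the plasmid there were 10 junctions where 11.8 were expected, a ratio of 0.849 (0.407 to 1.56) with an adjusted p of 0.892. Low-copy repeats, at 1.6 to 8 copies, joined each other in 13 junctions against 2.51 expected, 5.18-fold (2.76 to 8.86, adjusted p 6e-05). Joins between neighbouring fragments of a contig count in this excess as well. How much of it they make up was not tested, so it does not show that separate repeats met. High-copy repeats, the class of Ty-like depth at 8 to 50 copies, joined the 2-micron plasmid in 11 junctions against 3.09 expected, 3.56-fold (1.78 to 6.38, adjusted p 0.0014). Short pieces of the plasmid or of the rDNA could fall in that class, because classes rest on depth and GC content alone. None of the 16 chromosomes was favoured by rDNA ends. Chromosome XII, which carries the rDNA, had 3 junctions with it against 4.25 expected (0.706-fold, 0.146 to 2.06), and every adjusted p over the 16 chromosomes was 1.

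**Figure D2:**
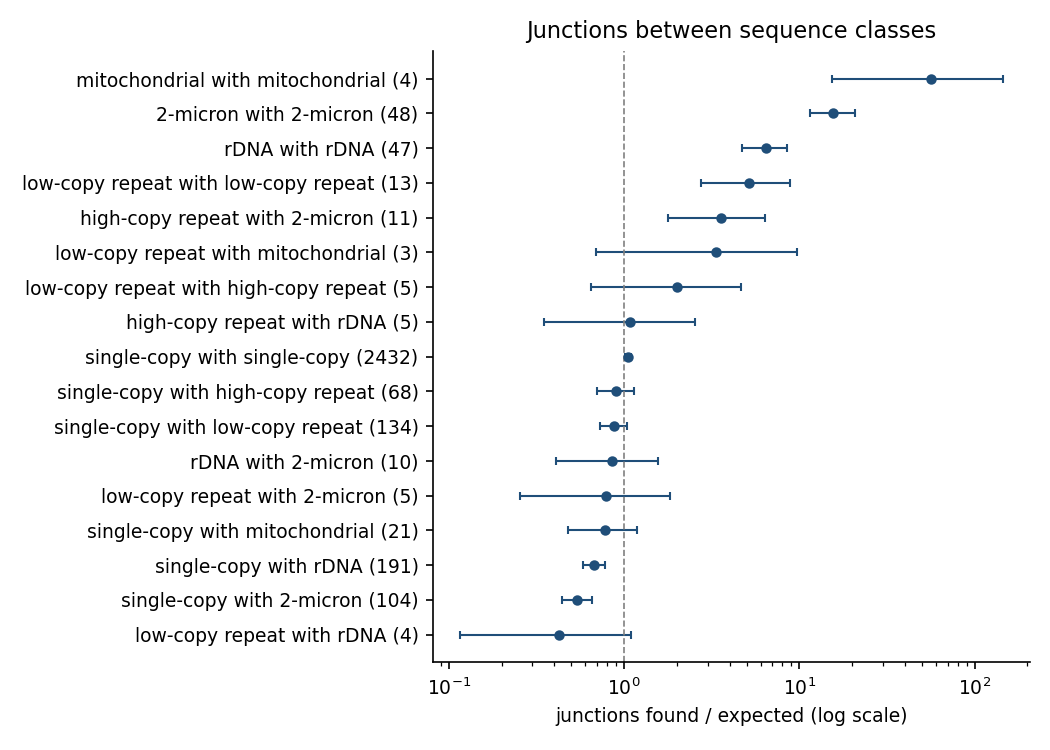
Ratio of junctions found to junctions expected from shuffled partners (horizontal axis, log scale) for each tested pair of sequence classes with at least 1 junction, with 95% Poisson intervals. The number in brackets is the number of junctions and the dashed line marks 1. The 2-micron plasmid with itself stands at 15.6 and the rDNA with itself at 6.41, while their ratios with single-copy sequence are 0.540 and 0.674.

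Among ends in site reads with both parts matched, the share joined to another partner depended on how reads were counted. Ends cut and left open are not counted among them. With every read counted, joined ends were 12.5% of single-copy ends (12.2% to 12.8%), 10.3% of rDNA ends (9.42% to 11.3%), 13.0% of mitochondrial ends (9.69% to 17.3%) and 18.5% of 2-micron ends (16.7% to 20.4%). With identical reads counted once, as for the other junction results, the shares were 13.3%, 65.6%, 21.9% and 58.2% in the same order. The few sequences possible at an intact rDNA or plasmid site run out under that counting, so the classes are not compared on it.

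The fifth comparison asked whether mitochondrial DNA, which lies in its own compartment, was joined to the nuclear genome. Mitochondrial ends took part in 28 of the 3221 junctions (0.869%, 0.602% to 1.25%). In 24 of these the partner was nuclear, against 31.8 from shuffled partners, a ratio of 0.754 with a Poisson interval of 0.483 to 1.12. The permutation p was 2e-05, the smallest possible, because 95% of shuffles gave 30 to 32 such junctions. With a limit of 28% GC for mitochondrial pieces the ratio was 0.920 and the p 0.0849, so the call depends on how the class is drawn. Single-copy ends of different nuclear contigs had a ratio of 0.978 (0.938 to 1.02), with the same smallest permutation p. The difference for the mitochondrion rested on 4 junctions between mitochondrial ends, where 0.071 were expected, 56.4-fold (15.4 to 144). These 4 junctions joined 3 different pairs of ends, and 3 of the 4 used a piece that carries part of COX1. Both pieces stood at 2.5 copies or more in 2 of them. Joins between neighbouring fragments were not set apart here either.

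The mitochondrial class was not pure. By protein match it held a piece with the nuclear gene CUP1-1, while OLI1 and a part each of COX1 and COX2 lay on pieces in nuclear repeat classes. These 4 pieces had 0 MspI sites and entered no junction, but other pieces in the wrong class cannot be excluded.

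Among mitochondrial genes, COX1 lay on mitochondrial pieces with 2 MspI sites that held 10 junction ends, and COB on pieces with 1 site and 1 junction end. A single-copy piece that matched COX1 at 90% identity is not counted. The pieces that matched COX2, COX3, ATP6 and OLI1 held 0 sites, so no junction could be read there. ATP8, VAR1 and the mitochondrial ribosomal RNA genes were not analysed here. The nuclear partners of mitochondrial ends did not differ detectably from nuclear partners in general for any of 6 classes (Fisher's exact test, two-sided, 24 partners). The nearest to a difference was low-copy repeats, with 3 of 24 mitochondrial partners (12.5%) against 170 of 6016 other ends (2.83%), p 0.0301 and adjusted p 0.180. The piece of 1 of these 3 partners had 23.98% GC, so its nuclear origin is not certain. With the 28% GC limit low-copy repeats passed the threshold (6 of 22, 27.3%, adjusted p 0.000199), but that limit moves a COX1 piece of 29.7% GC into this class. The nuclear genes that could be located on contigs joined to mitochondrial ends were MGR2 and INA17 on chromosome XVI, and YBL071C and KTI11 on chromosome II. MGR2 and INA17 shared a contig, as did YBL071C and KTI11. Only YBL071C held an MspI site (1) and a junction end (1) inside the gene, and the others held 0.

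The sixth comparison asked whether any pair of loci was joined again and again. Of 2264 single-copy junctions between contigs, 2218 contig pairs had at least 1, and 44 had 2 or more. A pair of contigs with 3 junctions occurred 2 times, each with 0.00265 junctions expected and an adjusted p of 0.00597 in a one-sided exact Poisson test over 3854476 possible pairs. In both pairs the 3 junctions used 3 different pairs of ends. The number depends on the settings, with 8 pairs at 10 bases beyond the site, 0 at 14, 417 with 1 mismatch per part and 573 with every read counted. None of these contigs could be placed, so no gene is named, and it is not known whether the contigs of a pair are neighbours on a chromosome.

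The seventh comparison asked how many ends MspI had cut without ligase closing them. A read that starts exactly at the cut begins with CGG and lacks the full site. Such reads stood at 4.98 per single-copy MspI end, against 0.196 per position 5 to 20 bases away, 25.4-fold (25.2 to 25.5, exact Poisson). The excess was 89.4-fold (88.6 to 90.3) in rDNA, 82.0-fold (79.02 to 84.98) in mitochondrial DNA and 14.8-fold (14.3 to 15.3) in the 2-micron plasmid. Against positions 21 to 60 bases away, which not every end has, it was 115-fold in rDNA, 55.3-fold in mitochondrial DNA and 13.2-fold in the plasmid. At single-copy ends it was 19.6-fold. The background there was 0.186, but reads per end were 3.65 over 18608 ends, against 4.98 over 20467 ends in the first measure. The single-copy excess thus depends on which ends are counted. The rDNA and plasmid values rested on 18 and 16 ends in the first measure and 15 each in the other. The mitochondrial value rested on few ends as well, with 71.5 reads per end over 41 ends in the first measure and 17.8 over 29 ends in the other. Over all reads without a site, 4.24% began with CGG, while 0.608% began with GGC, a 6.97-fold difference.

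The eighth comparison checked the strain, which per the labels lacks MET17 (named MET15 there), URA3, LEU2 and part of HIS3. Reads were searched for stretches of 9 residues of each protein and scaled to 6 single-copy control genes (PGK1, TRP1, GCN4, SOD1, CYC1 and TPI1). MET17 matched 0 reads, which allows up to 0.00126 copies if the probe is right. Its probe differs in length from the gene table (1344 against 1335 bases), and a wrong probe would match no read either. URA3 matched 4 reads (0.0081 copies, 0.00222 to 0.0208). LEU2 matched 7 reads, all at 1 stretch (0.0030 copies, 0.00119 to 0.00609). HIS3 behaved otherwise, with 282 reads and 0.585 copies (0.518 to 0.657). Its reads covered both ends of the gene, and 70 stretches in a row matched no read, which leaves residues 104 to 165, a span of 62 residues or 186 bases, without a read. Outside that gap HIS3 stood at 0.873 copies. The control genes lay between 0.959 (TRP1) and 1.10 (SOD1) copies.

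**Figure D3:**
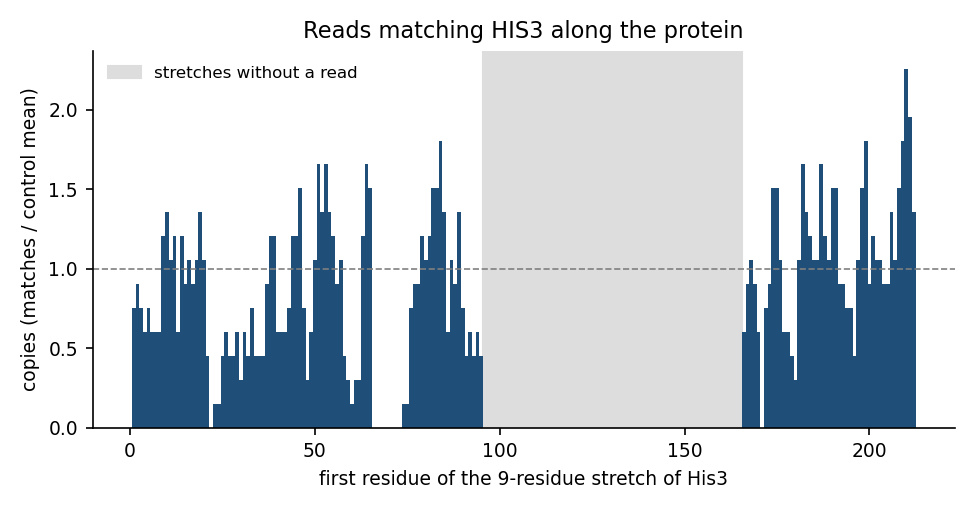
Copies of each 9-residue stretch of the His3 protein (vertical axis, matches divided by the mean of the 6 control genes) along the protein (horizontal axis, first residue of the stretch), with the 70 stretches in a row without a read shaded. The stretches outside the shaded part averaged 0.873 copies.

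The ninth comparison asked how many copies of each kind of DNA the culture held, relative to single-copy contigs. The rDNA stood at 205 copies (204 to 206), the 2-micron plasmid at 65.2 (64.9 to 65.5) and mitochondrial DNA at 4.77 (4.74 to 4.79). These intervals take the classes as given, and classes were drawn by depth, so the values are bounded by the class limits. Pieces with the 3' end of the 18S ribosomal RNA at 39.3, 39.8 and 61.5 copies were left out of the rDNA in this way. The mitochondrial class was mixed, with piece quartiles of 0.733, 1.57 and 4.14 copies, and it stood at 2.64 copies at mapping quality 20 and 1.83 with identical reads once. Counting only MspI sites with at least 20 bases of contig on both sides, mitochondrial DNA had 0.312 sites per kb and single-copy sequence 0.998. Their GC contents were 14.3% and 38.2%. The rDNA had 2.32 such sites per kb. Sites nearer a contig end are missed, which may lower these densities most in classes made of short pieces. Windows with CCGG were not left out of these class depths, which lowers the values of classes with many sites. Protein matches, which need no assembly, gave 64.01 copies of FLP1 (63.5 to 64.5), 28.2 copies of the Ty1 gene TYA1 (27.8 to 28.5) and 7.14 copies of CUP1-1 (6.68 to 7.63). The mitochondrial genes ranged from 5.11 copies for COX1 and 6.07 for ATP6 to 8.70 for COX2 and 11.3 for COX3. Stretches without any read count in these means. In COX1 84.3% of stretches matched a read, against 96.4% in ATP6, 100% in COX2 and 96.6% in COX3. The lower place of COX1 is therefore not a like comparison. Histone genes HHT1 and HHF1 gave 1.37 and 1.42 copies, and ADH1 and TDH3 gave 2.04 and 2.33, in each case with related genes whose reads match the same stretches.

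Read depth was also compared between nuclear genes. Whole genes could be located on placed contigs for 684 protein-coding genes, which had a median of 1.14 copies and a range from 0.877 to 1.56 between the 5th and 95th percentiles. Gene depth left out windows with CCGG, but the median it was divided by did not, which raises the gene values. The lowest were YDR029W (0.698, 0.548 to 0.876), FYV7 (0.709), MRP21 (0.732), TMH18 (0.734), PCP1 (0.740), YPR053C (0.747), YOL024W (0.753), RPS31 (0.761), COX16 (0.763) and YEL014C (0.766). The highest were RSO55 (4.64, 4.27 to 5.04), ASP3-1 (4.51, 4.30 to 4.73), BOL3 (3.59), FMT1 (2.77), YDR215C (2.42), SHR5 (2.18), DEP1 (2.09), YLR112W (2.04), DSK2 (2.00) and FMP46 (1.88). Depth rose with GC content across genes (Spearman's rho 0.415), and genes are not independent replicates.

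Most of the high values came from reads that start at cut MspI ends. Without those reads, RSO55 stood at 1.23 copies (1.04 to 1.45), BOL3 at 1.18 (0.948 to 1.44) and FMT1 at 1.39 (1.27 to 1.52), and of the 9 genes above 2 copies only ASP3-1 stayed there, at 4.57 (4.35 to 4.79). The gene table lists 4 ASP3 genes on chromosome XII. FMP46, which has 0 MspI sites, stood at 1.92 copies (1.69 to 2.16). The 10 lowest genes moved little and lay between 0.713 (YDR029W) and 0.779 (COX16).

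**Figure D4:**
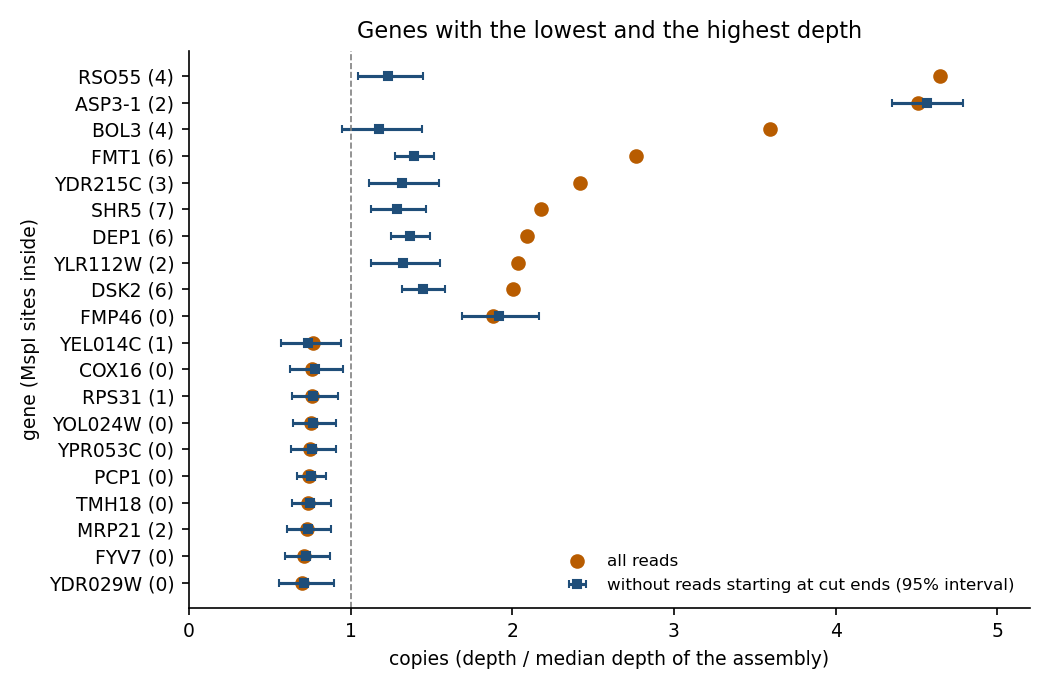
Copies (horizontal axis, depth divided by the median depth of the assembly) of the 10 genes with the lowest and the 10 with the highest depth, with the number of MspI sites inside each gene in brackets; circles use all reads and squares leave out reads that start at cut ends, with 95% Poisson intervals. RSO55 moved from 4.64 to 1.23, while ASP3-1 stood at 4.51 and 4.57.

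Few members of the gene lists could be located. Of 138 cytosolic ribosomal protein genes 5 were, with 5 MspI sites and 3 junction ends: RPL10 at 1.66 copies held 2 of these ends, RPP0 at 1.30 held 1, and RPL3 (1.23), RPS12 (1.21) and RPS31 (0.761) held 0. The nuclear genes of oxidative phosphorylation ATP7 (1.10), COX6 (1.05) and QCR10 (1.11) held 0 junction ends, but they had 1 MspI site in all, in ATP7. Of the subtelomeric families, COS111 (1.15 copies) had 6 sites and 2 junction ends. No gene of glycolysis, of the hexose transporters, of the histones or of the galactose pathway was located, so no list could be tested for junctions among its members.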

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

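Of 75 alternative values, 52 kept their direction and their side of the threshold or stayed inside the interval of the main value. The site share reversed, from 0.993 to 1.05 times the expected with identical reads once, and the cause was not tested. Against the weighted expectation the same counting gave 0.965, with no reversal. No other value reversed. The alternatives chosen after the data were seen were the placement margin of 8, the 28% GC limit, end pairs seen 3 or more times left out, cut-end reads left out, and every alternative for junctions within a contig, between contigs of a chromosome and of the plasmid with itself.

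Under all alternatives run, the excess of same-chromosome junctions ranged from 13.2-fold to 18.2-fold, that between different contigs from 3.62-fold to 5.803-fold, that of rDNA with rDNA from 5.68-fold to 6.90-fold, and that of the plasmid with itself from 12.2-fold to 16.7-fold, all with permutation p values of 0.0003 or less. The within-contig excess ranged from 196-fold to 414-fold.

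The slope with distance was -2.27 from 5 to 200 kb (13 junctions) and -1.01 with 14 bases, and the cause was not tested. The ratio of mitochondrial with nuclear junctions rose to 0.920 with a permutation p of 0.0849 under the 28% GC limit, which leaves out the COX1 piece of 29.7% GC used by 3 of the 4 mitochondrial with mitochondrial junctions. Under the same limit, 1 class of nuclear partners, low-copy repeats, passed the threshold in place of 0, and that class then holds the COX1 piece. The p of the ratio was 0.00134 or less under the other alternatives.

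Repeated contig pairs numbered 8 with 10 bases, 0 with 14 bases, 573 with every read counted and 417 with 1 mismatch, against 2. Every read counted lets identical reads count as separate junctions by construction. For the others the cause was not tested. The junction share was 12.4% with every read counted. The site share stood at 0.915 times the expected under depth weighting. The excess at single-copy cut ends was 19.6-fold against the background 21 to 60 bases away, where that of rDNA rose to 115-fold and that of mitochondrial DNA fell to 55.3-fold. That measure also covers fewer ends, and at single-copy ends the reads per end changed more than the background.

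Mitochondrial depth was 1.83 copies with identical reads once, 2.64 with mapping quality of 20 or more, 3.79 with GC correction and 4.67 without cut-end reads. The rDNA stood at 6.32, 167, 188 and 181 copies in the same order, and the plasmid at 5.97 with identical reads once, 44.7 with mapping quality and 62.7 without cut-end reads. Identical reads counted once saturate in repeated sequence by construction. For the other changes the cause was not tested.

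Not run were all alternatives for centromere, chromosome-end and gene-list junctions, including windows of 10 and 50 kb and ends within 2 kb of a gene, bins of 20 kb for repeated junctions, aligned reads for the deleted genes and windows of 50 kb for depth. Depth limits the mitochondrial result, which has 28 junctions, and distances beyond 46.4 kb.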

Other observations

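The tests below were chosen after the result was seen, except that of plasmid ends joined to themselves and the limits of 20% and 40% in the next paragraph. The design has no groups, so no biological explanation from the design was tested.

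Junctions within a contig exceeded shuffled partners 399-fold. Gaps or deletions in the assembly could be read as such junctions, and they would join the upstream flank of the first site to the downstream flank of the second. Junctions of 2 upstream or 2 downstream flanks, which a deletion cannot make, numbered 58 of 168 (34.5%, 27.75% to 41.99%). The share lay between the limits set before it was counted, below 20% if such errors were the source and above 40% if not, and its interval holds the upper limit. By those limits the question stays open. As the interval lies above 20%, such errors do not account for all of the excess, a reading chosen after the value was seen. Among the 110 junctions of opposite sides, 48.2% had the deletion orientation (39.1% to 57.4%). This share cannot decide on a smaller contribution of such errors. The other orientation, in 57 junctions, can also hold circles over several fragments, because only circles of single fragments were left out. The deletion orientation had 53 junctions, against 24 of 2 upstream and 34 of 2 downstream flanks.

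The 2-micron plasmid joined itself 15.6-fold more often than shuffled partners. A few unrecognised neighbouring ends could give such an excess, but without end pairs seen 3 or more times it was still 12.2-fold. Often repeated pairs alone therefore do not account for it. Neighbouring ends joined fewer times stay in that value, so they are not excluded. Joining within a single circle was to be tested by junctions of a plasmid end with another copy of itself, of which 3 were found (0.619 to 8.77) and 6.76 expected from random pairing among plasmid ends. All 3 lay on the contig with the plasmid's recombination target, which is part of a repeat present in 2 copies on each circle. Whether these ends lie inside the repeat was not checked. If they do, such junctions can arise within a circle, so the test decides nothing. Elsewhere on the plasmid 0 were found, which allows up to 3.69, where 4.51 were expected. This count was looked up afterwards, and joining within a circle and between plasmids cannot be told apart.

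The 9 genes above 2 copies each held several MspI sites. Other genes with many sites did not have high depth, such as KEX2 (6 sites, 1.13 copies) and ERG7 (8 sites, 1.28 copies). Reads that start at cut ends are a candidate explanation of the high values. Without them, 1 of the 9 genes above 2 copies stayed above 2, and the correlation of depth with the number of sites across the 684 genes fell from 0.288 to 0.066. GC content alone would have left these genes high, but their median without such reads was 1.33 copies. Across the 684 genes the correlation of depth with GC content stayed at 0.340, from 0.415, so GC content may still add to their depth. The exception, ASP3-1, stood at 1.14 copies per listed ASP3 gene, which is consistent with reads of 4 listed genes on 1 assembled copy. The value for FMP46, without any site, stays open.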
